A study of Caenorhabditis elegans with 2 samples.

How the data were processed

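ChIP-seq of GFP-tagged UNC-130 was performed on 2 biological replicates of whole young adult hermaphrodites, per the labels. The replicate numbers were taken from the labels, which name separate worm samples for each. The labels describe the antibody as directed against GFP in 1 field and name unc-130 in another; the first is followed here. Chromatin was fragmented by sonication, per the labels.

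For each replicate and for the pooled replicates the authors deposited a list of candidate regions, peaks together with background, made as input for the irreproducible discovery rate (IDR) procedure, which compares the ranks of peaks in the replicates. They also deposited a final list of optimal IDR peaks; it equals the pooled regions at or above a single signal value, so a single member need not rank alike in both replicates. Each list exists on the ce10 and ce11 builds. The deposited listings name the alignments of the replicates and 1 control file as the origin of each list; the aligner, the peak caller, its version and the IDR threshold are not given in the sources used here. The signal value of each region is the authors' own, on a scale that the sources used here do not give, so it is used to rank and describe regions within a list, and between replicates only through ranks; values of the replicates are given side by side without a ratio. In the comparison of builds the lowest optimal ce10 value was also applied to the pooled ce11 list. The deposited −log10 q-value of each region was at its highest value, 3.56, for all 1168 optimal ce11 peaks and was not used further. The summit is the deposited offset from the region's start, which falls under no other unit. The lists hold no read counts, so the depth of each replicate is unknown; intervals are 95% Wilson intervals over regions and cover counting error only. Files or columns without a sample or pool numbered 0. Read alignments and the control were not analysed here.

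The tests used the ce11 lists and the WBcel235 genome and annotation, which is the same assembly, except that the chromosome test was repeated on the ce10 lists; region ends lay within the chromosome lengths. The ce10 lists were used for number, width, signal and chromosome only, and no coordinates were converted. Coordinates are 1-based. Some regions carry more than 1 summit, so the 1168 optimal entries are 1153 distinct regions, and entries were counted. The background was the 20584 pooled regions that overlapped no optimal peak. Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family of 7 chromosomes, 10 classes, 2 measures of 21U-RNA loci or 17 gene lists. Summits were assigned to a promoter window (1000 bp upstream to 200 bp downstream of a protein-coding transcript start), else exon, else intron, else intergenic sequence, and separately to noncoding genes within 200 bp. The 21U-RNA domains were bins of 100000 bp on chromosome IV with 20 or more 21U-RNA genes, joined over gaps of up to 500000 bp.

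Strings were counted on both strands in 200 bp summit windows and compared with 10000 draws of background windows matched within 10 GC classes. The p-value is the two-sided rank of the peak count among these draws, called permutation p in this text. The smallest possible is 2e-04 before adjustment. Labels were permuted only in the setting of that name, and otherwise the draws leave out the counting error of the peaks. Permuted labels gave the forkhead consensus an adjusted p of 0.11 by permutation. Mean GC content was 40.2% in peak windows and 37.4% in background windows. Replicate overlap and 21U-RNA overlap were also compared with 1000 circular shifts along each chromosome. Gene lists were tested among genes with a pooled region in the promoter window, and genes are not independent replicates. Symbols of the lists that the annotation does not hold numbered 2. A peak was assigned to every promoter window that its summit fell in; 308 summits fell in windows of more than 1 gene.

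The design, the lists and the alternatives were fixed before the data were examined, except where the text says otherwise. Named genes were the 20 optimal peaks of highest signal, each named by the nearest protein-coding start within 2000 bp; up to 4 members of each list with the highest signal; unc-130, mex-5, tbb-2, unc-129 and prg-1; and 3 peaks of highest signal in the 21U-RNA domains. Mitochondrial genes were named from the RefSeq annotation at the summit. Alternatives were each replicate alone (its 1168 best regions), the 584 peaks of highest signal, other promoter windows (500 and 2000 bp upstream), other motif windows (100 and 400 bp), other backgrounds, other overlap rules and the ce10 lists. Alternatives added after the data were seen were nuclear chromosomes only, promoter summits only for the strings, labels permuted within GC classes, the germline list without mex-5, that list without mex-5 and rec-8, which share a peak, strings away from tRNA genes, and strings in windows matched on the number of CG dinucleotides. With 1 group there is no comparison between groups of samples, and p-values measure how peaks differ from background regions within this experiment.

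The tests were tested on simulated data. In 100 random draws of 1168 regions from the 22082 nuclear pooled regions, the motif test called 6% of sets with no planted string. It called 100% of sets in which the forkhead string was planted in 10% of windows, with a mean excess found of 9.70 percentage points. These calls used a permutation p under 0.05 without adjustment. Random draws have no built-in GC difference from their background, so they did not test the GC matching. The chromosome, class and 21U-RNA tests made 1 or more calls in 3%, 4% and 4% of 100 such random sets, and the gene list test in 2% of 100 random sets over 7296 genes. Moving 2% of peaks onto 21U-RNA genes was called in 93% of sets. A ribosomal list with peaks at 30% of its members was called in 64% of sets. That check used a cut-off of 0.05 divided by the 17 lists, not the Benjamini-Hochberg adjustment. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.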

Results

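Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where UNC-130, a forkhead transcription factor, was found on the genome of young adult Caenorhabditis elegans hermaphrodites. The factor carried a green fluorescent protein (GFP) tag and was expressed from a transgene under the promoter of mex-5, a germline gene, with the 3′ UTR of the tubulin gene tbb-2. Whole worms were collected 56 hours after synchronization as starved first-stage larvae, and the tagged protein was recovered with an antibody against GFP. The series held 1 group of 2 biological replicates and no second condition, so the comparisons below set the final peaks against weaker candidate regions of the same experiment and set the replicates against each other. The files hold region lists and no read counts, so the depth of each replicate is unknown and the intervals given for shares cover counting of regions only. The lists of replicates 1 and 2 held 21622 and 20625 candidate regions on the ce11 build, the list from the pooled replicates 22106, and the authors' final list of optimal peaks 1168. The 20584 pooled regions that overlapped no optimal peak served as background. Each signal value is the authors' peak caller's own value and is used here only to rank and describe regions.

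The strongest peaks lay on the mitochondrial genome, and the strongest nuclear peaks lay at promoters of protein-coding genes, several of them for ribosomal proteins. The 13 peaks of highest signal were all mitochondrial, led by a summit at position 4733 in the cytochrome b gene CYTB (signal 3682; 2160 in replicate 1 and 1565 in replicate 2) and 1 at position 12392 in ND5, a subunit of respiratory complex I (signal 1957; 1121 and 876). Together 23 mitochondrial entries covered 89.9% of that genome of 13794 bp, against 0.225% of chromosome X and 0.662% of chromosome III. The nuclear peak of highest signal (390; 209.8 and 180.5 in replicates 1 and 2) was at III:8043787–8044136, 520 bp from the nearest transcript start, that of the uncharacterized gene K12H4.5. It was followed by peaks at tasp-1, a homolog of the protease taspase (III:10759046–10759417, signal 357), and at the large-subunit ribosomal protein genes rpl-3 (III:3867399–3867731, 348), rpl-35 (III:7854542–7854856, 295) and rpl-15 (IV:654746–655081, 248).

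The rule for named genes took the 20 peaks of highest signal, most of them mitochondrial, so the 25 nuclear peaks of highest signal were also listed, a choice made after the values were seen. Among these were the MADF-domain gene madf-6 (I:1014332–1014725, signal 237), cdc-48.1, which encodes an ATPase that extracts ubiquitinated proteins (II:10563447–10563709, 224), and mog-4, a splicing helicase needed for the switch from sperm to oocytes (II:14561657–14561996, 223). The eggshell chondroitin proteoglycan gene cpg-1 (III:4489007–4489288, 219), the caveolin gene cav-2 (V:13556742–13556953, 197) and the kinesin gene klp-16 (I:9512275–9512503, 183) were also on this list. A second peak at lea-1 lay in an intron, 2013 bp from the transcript start (V:10018395–10018612, 183).

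Chromosome X carried fewer optimal peaks than its share of candidate regions. Its 94 peaks were 8.05% of the total (95% Wilson interval 6.62–9.75), against 12.1% of background regions (Fisher's exact test, two-sided, adjusted p = 5.2e-05 over 7 chromosomes), a fold of 0.664 that was 0.367 among the 584 peaks of highest signal. Chromosome V was also lower, with 159 peaks or 13.6% against 17.1% (Fisher's exact adjusted p = 0.0046), a call that ended in that stricter set (Fisher's exact adjusted p = 0.113). Chromosomes I, II, III and IV held 240, 214, 237 and 201 peaks and did not pass the test. Chromosome I passed on the replicate 1 list alone (fold 1.20, Fisher's exact adjusted p = 0.0038), and chromosome III on each replicate's list alone, with folds of 1.22 on that of replicate 2 (Fisher's exact adjusted p = 0.0019) and 1.20 on that of replicate 1 (0.0040). Chromosome III also passed on ce10 (fold 1.15, Fisher's exact adjusted p = 0.0171), and chromosomes I, II and III passed against the expectation from chromosome length.

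The replicates shared most of their strongest regions. Of the 1168 best regions of replicate 1, 69.4% overlapped one of the 1168 best of replicate 2 by 1 bp or more, and 70.03% in the other direction. Circular shifts of the regions along each chromosome gave 3.02% on average and 4.28% at most (permutation p = 0.002, two-sided, the smallest that 1000 shifts can give). On nuclear chromosomes only, 68.9% of the 1145 best regions of replicate 1 overlapped, against 1.11% on average for the shifts. The shifts ignore where genes lie, so a preference of both lists for promoters would also exceed them. Of the optimal peaks, 966 lay among the 1168 best regions of replicate 1, 938 among those of replicate 2 and 760 among both. The optimal peaks are the top of the list made from both replicates pooled, so these 3 counts are partly built in. Across the 1144 nuclear peaks matched in both lists, Spearman's rho of the signal values was 0.475, a value across peaks that are not independent replicates.

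**Figure D1:**
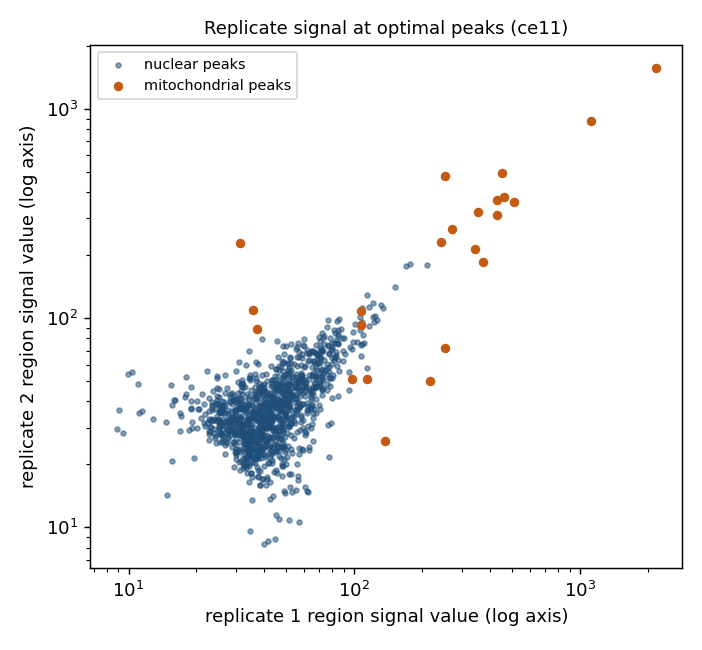
Signal value of the region matched to each optimal peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), in the authors' signal units; each point is 1 peak. The mitochondrial peaks reach 2160 and 1565, and the nuclear peak of highest signal lies at 209.8 and 180.5.

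Optimal peaks were concentrated at promoters of protein-coding genes and near small structural RNA genes. A promoter window, from 1000 bp upstream to 200 bp downstream of a transcript start, held 780 summits, 66.8% (95% Wilson interval 64.03–69.4) against 35.6% of background summits (1.88-fold, Fisher's exact adjusted p = 5.4e-97 over 10 classes). Exons held 5.39% against 23.7% (0.228-fold, and 0.365 on the replicate 2 regions alone), introns 10.7% against 22.2%, and intergenic sequence 17.1% against 18.6%, of which intergenic sequence alone did not pass the test (Fisher's exact adjusted p = 0.230). It did pass, as lower, on the replicate 2 regions alone (0.830-fold, Fisher's exact adjusted p = 0.0049), among the 584 peaks of highest signal (0.811-fold, 0.038) and against circular shifts (0.737-fold, permutation adjusted p = 0.0025). The median nuclear summit lay 324 bp from the nearest transcript start (quartiles 150 and 1034 bp).

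Summits within 200 bp of a tRNA gene made up 13.6% of peaks against 1.65% of background (8.24-fold, Fisher's exact adjusted p = 1.8e-79), and those near snoRNA genes, whose RNAs guide modification of ribosomal RNA, 6.08% against 0.432% (14.1-fold, adjusted p = 7.5e-47 by the same exact test). Genes of spliceosomal and other snRNAs had 28 peaks nearby, 2.40% against 0.345% (6.95-fold, Fisher's exact adjusted p = 3.0e-13). These folds depended on the setting. For tRNA genes the fold was 7.88 on nuclear chromosomes only (149 of 1145 peaks), 4.25 among the 584 peaks of highest signal and 15.3 against circular shifts. Against circular shifts it was 30.3 for snoRNA and 35.2 for snRNA genes. Counted by gene, 164 of 612 nuclear tRNA genes (26.8%, 95% Wilson interval 23.4–30.4), 70 of 346 snoRNA genes (20.2%) and 17.8% of snRNA genes had an optimal summit within 200 bp. Many tRNA and snRNA genes have near-identical copies, so which copy a peak belongs to is uncertain. The 6 peaks near microRNA genes did not pass the test (2.35-fold, Fisher's exact adjusted p = 0.061) but did on the replicate 2 regions alone (3.67-fold, 0.0019 by the same exact test) and against circular shifts (4.42-fold, permutation adjusted p = 0.0067); the 5 near ribosomal RNA genes were mitochondrial.

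**Figure D2:**
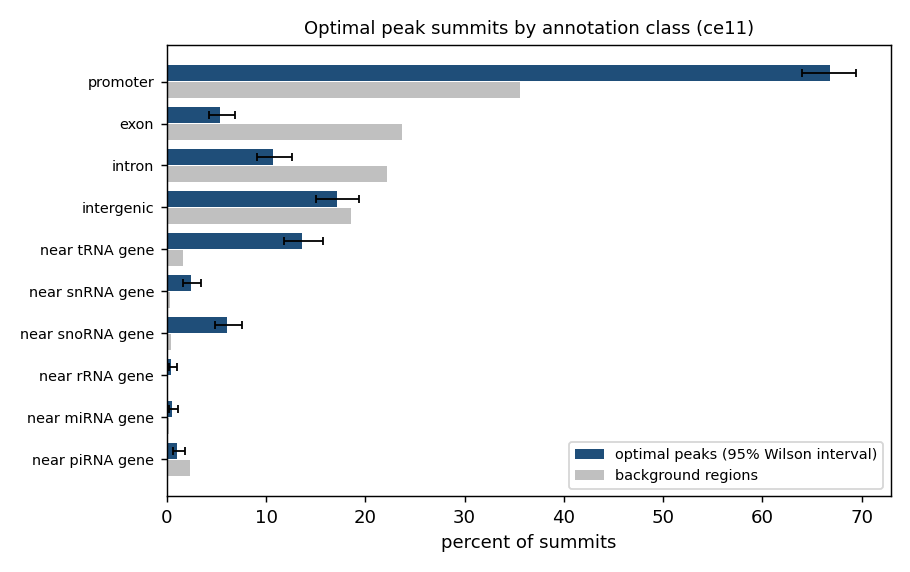
Percent of summits (x axis) in each annotation class (y axis) for the 1168 optimal peaks (dark bars, error bars are 95% Wilson intervals) and the 20584 background regions (grey bars); the classes near noncoding genes count summits within 200 bp and overlap the other classes. Promoters held 66.8% of peaks and 35.6% of background summits.

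Genes of the germline, of the cell cycle and of the ribosome had promoter peaks more often than other genes. In all, 1068 of 7296 protein-coding genes with a candidate region in the promoter window had an optimal summit there (14.6%). Among genes of the germline, meiosis and oogenesis 15 of 30 tested members did (50%, 95% Wilson interval 33.2–66.8, odds ratio 5.90, Fisher's exact adjusted p = 8.3e-05 over 17 lists). These included cpg-1 and cpg-2, both of which encode eggshell proteoglycans (signal 219 and 160), and mex-1 and pos-1, which encode zinc-finger proteins of oocytes and early embryos (146 and 142). The list holds mex-5, whose promoter is part of the transgene; without it 14 of 29 members had a peak (Fisher's exact adjusted p = 2.5e-04). The meiotic cohesin gene rec-8 is counted through the same peak, and without both 13 of 28 members had one (46.4%, Fisher's exact adjusted p = 3.5e-04). The share of germline members with a peak was 3.45 times that of other genes with a candidate region, and 8.83 times with all protein-coding genes as background.

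Among genes of the cell cycle and DNA replication, 10 of 18 tested members had a promoter peak (55.6%, 95% Wilson interval 33.7–75.4, odds ratio 7.35, Fisher's exact adjusted p = 3.5e-04). The members of highest signal were lin-35, the worm homolog of the retinoblastoma protein (I:5807435–5807625, signal 179), mcm-2, a subunit of the replicative helicase (II:12006762–12006960, 143), pcn-1, which encodes the sliding clamp PCNA (IV:4049631–4049781, 126), and the mitotic kinase gene cdk-1 (III:9746647–9747076, 73.0). Among the 584 optimal peaks of highest signal this call ended, with 3 of 18 members (2.05-fold against 3.82, Fisher's exact adjusted p = 0.548). Of the ribosomal protein genes 25 of 73 had a promoter peak (34.2%, 95% Wilson interval 24.4–45.7, odds ratio 3.09, Fisher's exact adjusted p = 2.5e-04), led by rpl-3, rpl-35, rpl-15 and rpl-20. With all protein-coding genes as background the folds rose from 3.82 to 9.38 for the cell cycle list and from 2.37 to 6.24 for the ribosomal list. The rpl-20 peak (IV:4749927–4750228, signal 244) also lay in the promoter window of its neighbour Y17G9B.5, rpl-24.1 and rps-10 share 1 peak, and the rpl-5 peak is also counted for the collagen gene col-38.

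Nuclear hormone receptor genes had promoter peaks less often, with 3 of 78 tested members (3.85%, 95% Wilson interval 1.32–10.7, Fisher's exact adjusted p = 0.0145), namely nhr-47, nhr-142 and nhr-255. This call did not hold in several other settings, among them the regions of replicate 1 alone (Fisher's exact adjusted p = 0.383). No optimal promoter peak was found at the 27 tested homeobox and neuronal identity genes (Fisher's exact adjusted p = 0.087), the 10 genes of the TGF-beta pathway, the 8 forkhead genes, the 6 intestine genes or the 3 pharynx genes. None of these 5 lists passed the test, although the homeobox list did with promoter windows of 2000 bp upstream (Fisher's exact adjusted p = 0.0369). The tagged protein came from a transgene under a germline promoter, and its expression by tissue was not measured here. Differences between gene lists, higher or lower, therefore cannot be separated from where the tagged protein was expressed.

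Of the germline small RNA pathway 7 of 24 members had a peak (29.2%, odds ratio 2.41, Fisher's exact adjusted p = 0.207), with the Argonaute genes hrde-1 (III:4176306–4176505, signal 153) and csr-1 (IV:7958168–7958597, 102) highest, followed by simr-1 (72.1) and znfx-1 (66.1). This list passed when all protein-coding genes were the background (4.85-fold, Fisher's exact adjusted p = 0.0018), while its fold of 2.00 fell to 1.48 with the nearest start only and to 1.02 among the 584 peaks of highest signal (2 of 24 members). The remaining lists did not pass. Peaks were at 4 of 16 sperm genes, among them spe-39 (signal 93.3, through a peak also counted for spn-4 of the germline list) and spe-9 (56.0). They were at 3 of 10 heat shock genes, with the mitochondrial chaperonin gene hsp-60 highest (228, through a peak whose nearest start is that of Y22D7AL.10). They were also at 4 of 24 histone genes, where his-67 and his-68 share 1 peak (120) and near-identical copies make the assignment uncertain. Among the tissue lists, peaks were at 5 of 38 collagen and epidermis genes (col-185 highest, 77.9), 1 of 13 body wall muscle genes (act-2, 75.4), 1 of 10 pan-neuronal genes (ehs-1, 56.1) and 1 of 3 genes of cell migration and axon guidance (unc-40, 61.9).

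**Figure D3:**
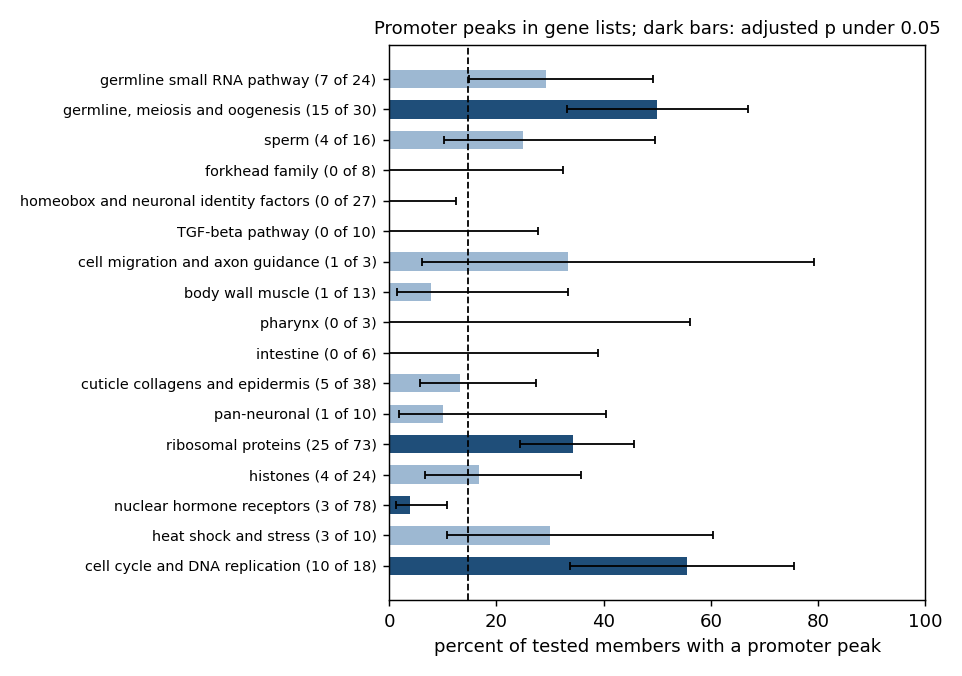
Percent of tested members of each gene list with an optimal summit in the promoter window (x axis), with 95% Wilson intervals and the counts beside each list (y axis); dark bars passed Fisher's exact test at an adjusted p under 0.05, and the dashed line is the share of other genes (14.6%, median over lists). The germline list reaches 50% and the nuclear hormone receptors 3.85%.

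The looser of 2 forkhead strings was modestly more frequent at summits than in background, and strings of the E2F type were more than doubled in frequency. In windows of 200 bp centred on the summit, the forkhead consensus GTAAACA occurred in 2.997% of peaks (95% Wilson interval 2.16–4.14) against 2.10% of background windows matched on GC content (1.43-fold, permutation adjusted p = 0.089 over 10 strings). The looser form RYMAACA occurred in 27.7% against 22.4% (1.23-fold, permutation adjusted p = 0.0013). The E2F string TTSSCGC, the binding site class of the cell cycle factors E2F and DP, occurred in 22.9% against 9.99% (2.30-fold, permutation adjusted p = 0.001; 3.97-fold against windows 500 bp to either side). The forkhead consensus did pass against windows 500 bp to either side of the same summits (1.89-fold, Fisher's exact adjusted p = 0.0126), in windows of 400 bp, on each replicate's own regions and with nuclear windows matched on CG dinucleotides (1.57-fold), a matching chosen after the data were seen. It did not pass at promoter summits (1.18-fold, permutation adjusted p = 0.663), among the 584 peaks of highest signal (1.37-fold, permutation adjusted p = 0.486), in windows of 100 bp (1.60-fold), without GC matching (1.41-fold) or away from tRNA genes (1.34-fold).

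The internal promoter element of tRNA genes, the B box GWTCRANNC, occurred in 19.7% of peaks against 10.3% (1.91-fold, permutation adjusted p = 0.001). Away from tRNA genes, a comparison added after the data were seen, it occurred in 8.84% of nuclear peaks against 8.51% (permutation adjusted p = 0.969). The GAGA string occurred in 19.5% against 15.6% (1.25-fold, permutation adjusted p = 0.0015), but did not pass in windows of 100 bp (0.992-fold) or at promoter summits (1.03-fold). The GATA string TGATAA (12.7% against 14.1%), the bZIP string TGASTCA (1.71% against 1.69%), the E-box CACGTG (4.45% against 4.77%) and the reversed forkhead control ACAAATG (4.37% against 4.31%) did not pass. GATA passed as lower in 4 other settings, among them promoter summits (0.751-fold, permutation adjusted p = 0.0110).

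**Figure D4:**
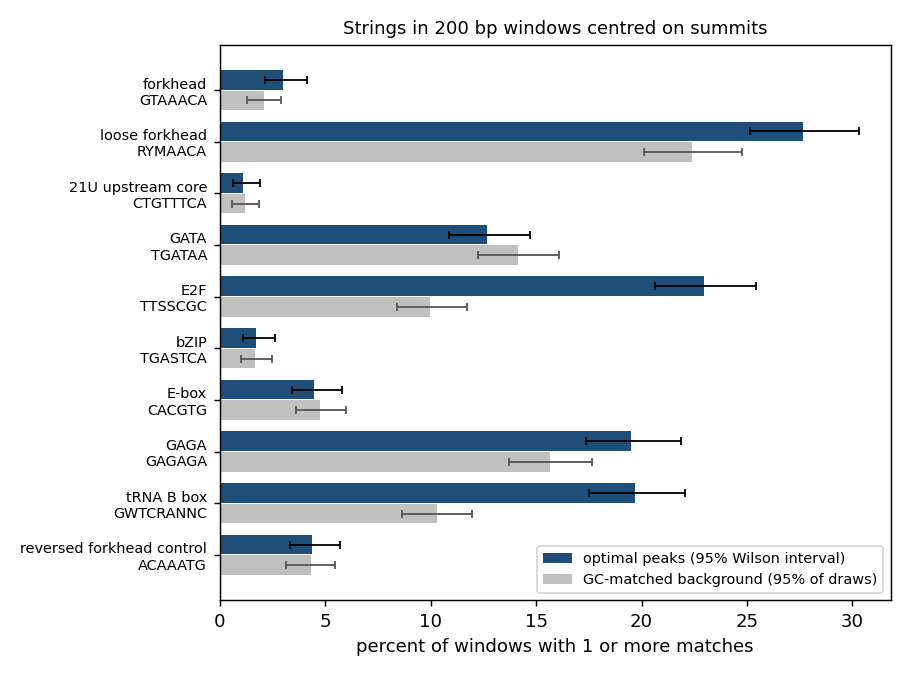
Percent of 200 bp summit windows with at least 1 match to each string on either strand (x axis) for optimal peaks (dark bars, 95% Wilson intervals) and for GC-matched background windows (grey bars, range of 95% of 10000 draws). The E2F string stands at 22.9% against 9.99% and the reversed forkhead control at 4.37% against 4.31%.

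Genes of 21U-RNAs, the piRNAs of this worm, were under-represented at peaks. Forkhead proteins have been described as binding upstream of individual 21U-RNA genes, and the germline expression of the transgene poses this question. Of the optimal peaks, 19 overlapped an annotated 21U-RNA gene extended by 100 bp, 1.63% (95% Wilson interval 1.04–2.53). The share of background regions was 3.04% (0.535-fold, Fisher's exact adjusted p = 0.0087). Circular shifts of the peaks gave 3.80% (95% range 2.48–5.05, permutation p = 0.004). The fold over background was 0.288 outside promoter windows, from 4 of 388 peaks. It was 0.700 for summits within 1000 bp of a 21U-RNA gene (Fisher's exact adjusted p = 0.045). On chromosome IV, where 14714 of the 15363 annotated 21U-RNA genes lie, 56 of 201 summits fell inside the 21U-RNA domains (27.9% against 30.4% of background, Fisher's exact adjusted p = 0.478). The domains were IV:4800001–7000000, IV:9100001–9200000 and IV:13500001–17300000.

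The upstream core CTGTTTCA of 21U-RNA genes occurred in 1.11% of summit windows against 1.22% (permutation adjusted p = 1). The domain peaks of highest signal were at promoters of protein-coding genes, namely Y73B6BL.29, a tRNA pseudouridine synthase (IV:6321790–6322045, signal 168), the ubiquitin hydrolase gene usp-4 (IV:6756553–6756749, 161) and C49A9.10 (IV:6206489–6206702, 150). The lower overlap with 21U-RNA genes did not pass the test among the 584 peaks of highest signal (0.514-fold, Fisher's exact adjusted p = 0.092).

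Of the annotated windows taken for the sequences that the transgene duplicates, the mex-5 promoter carried an optimal peak and the others did not. The ends of the fragments in the transgene may differ from these windows. Whether the transgene includes the optimal summit beyond the tbb-2 3′ UTR, given below, is therefore not known. The mex-5 peak (IV:13353332–13353527) had signal 135 and rank 110 of 1168, with 67.9 in replicate 1 and 67.8 in replicate 2. The lists do not separate signal of the transgene from that of the chromosomal copy there. The unc-130 gene (II:11281966–11283959) held no optimal or pooled summit; the nearest pooled summit lay 10 bp away (signal 14.7) and the nearest optimal summit 6621 bp away, and replicate 2 had a summit of signal 8.26 inside the gene (rank 16802 of 20625). In the tbb-2 3′ UTR (III:4015910–4016065) the pooled list had a summit of signal 46.3, below the lowest optimal signal of 53.5, which the replicates did not share alike (7.98 and rank 19443 of 21622 in replicate 1, 39.1 and rank 492 of 20625 in replicate 2), and an optimal summit of signal 148 lay 193 bp beyond it. The promoter of unc-129, a TGF-beta gene acting in axon guidance, and that of prg-1, the Argonaute that binds 21U-RNAs, held no pooled summit. Replicate 1 had a summit of signal 8.29 in the unc-129 promoter, the prg-1 gene itself held 4 pooled summits (highest signal 45.0), and an optimal summit of signal 109 lay 90 bp beyond it.

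The number of optimal peaks differed between the genome builds that the authors used. The ce10 list held 1485 peaks and the ce11 list 1168, with the same median width of 430 bp. Each list was the part of its pooled list above a single signal value, 46.8 on ce10 and 53.5 on ce11, and the ce10 value applied to the pooled ce11 list gave 1483 regions. Chromosome shares were similar, with X at 7.74% on ce10 and 8.05% on ce11.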

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

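Of the alternative values of results that answer a comparison or passed the main test, 168 kept their direction and their side of the threshold, 10 lost the call, 5 gained it and 3 reversed. Of the alternative values of the other results, 152 kept both, 18 gained a call and 21 reversed. Of the alternative counts of peaks or calls, 66 moved by 1.5 times or less and 16 by more. The promoter, tRNA, snoRNA, snRNA, E2F, loose forkhead, germline and ribosomal enrichments and the lower share on X passed under every alternative run for them. Their folds ranged over 1.499–2.46 for promoters, 4.25–15.3 for tRNA, 12.6–30.3 for snoRNA, 6.23–35.2 for snRNA, 1.82–3.97 for E2F, 1.16–1.37 for the loose forkhead string, 3.07–8.83 for the germline list, 2.30–6.24 for the ribosomal list and 0.367–0.677 for X. Intergenic sequence gained a call as lower on replicate 2 alone (0.830), in the 584 strongest peaks (0.811) and against circular shifts (0.737). The microRNA class gained a call on replicate 2 alone (3.67) and against circular shifts (4.42), and stood at 1.69 on replicate 1 alone. The causes of the changes below were not tested, except that the stricter set holds fewer peaks (584) and that leaving out the mitochondrial genome removes the 1 chromosome called higher. Nuclear chromosomes only, promoter summits only, permuted labels, strings away from tRNA genes, matching on CG dinucleotides and the germline list without mex-5 (3.33) or without mex-5 and rec-8 (3.20) were chosen after the data were seen. The unknown depth limits how weak a site can be and still be listed.

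Among the 584 peaks of highest signal, calls ended for chromosome V (0.828-fold, leaving 1 chromosome called lower), summits within 200 bp of a 21U-RNA gene (0.594), overlap with 21U-RNA genes (0.514, leaving 0 calls), the nuclear hormone receptors (0.156, leaving 0 lists called lower) and the cell cycle list (2.05). The cell migration list fell from above background to a fold of 0, from 1 gene. With promoters of 500 bp upstream, the nuclear hormone receptors were at 0.248 with 0 lists called lower, and intergenic sequence (1.02) and the heat shock list (0.734) reversed without a call. With 2000 bp upstream 2 lists were called lower. With all protein-coding genes as background the pan-neuronal list stood at 1.034.

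The forkhead consensus passed in windows of 400 bp (1.33), against flanking windows (1.89) and matched on CG dinucleotides (1.57), and did not in windows of 100 bp (1.60), without GC matching (1.41), away from tRNA genes (1.34), in the 584 strongest peaks (1.37) or at promoter summits (1.18). The GAGA string reversed in windows of 100 bp (0.992) and lost its call at promoter summits (1.03), as did the tRNA B box (1.25), leaving 2 strings called higher and 1, GATA, called lower. GATA was also the 1 string called lower without GC matching and against flanking windows. The B box also lost its call away from tRNA genes (1.04). Strings that were called in neither setting reversed as follows: matched on CG dinucleotides the 21U upstream core at 1.19 and GATA at 1.06; the E-box away from tRNA genes at 1.05; bZIP at 0.607 in 100 bp windows, 0.771 in 400 bp windows and 0.834 at promoter summits; the E-box at 1.16 in 100 bp windows, 1.10 without GC matching and 1.08 against flanks; the reversed forkhead control at 0.919 in 400 bp windows and 0.887 against flanks. Chromosome IV reversed on nuclear chromosomes only (1.02, with 0 chromosomes called higher) and on ce10 (1.03, with 2 called higher), and expectation from chromosome length gave 4 called higher.

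With each replicate's own regions in place of the optimal peaks, values ranged as follows. Chromosome IV stood at 0.994–1.06 with 2–3 chromosomes called higher, the forkhead consensus at 1.51–1.69 (called with both), the 21U upstream core at 0.734–1.18 (called with neither), bZIP at 0.816–0.962, the reversed forkhead control at 0.9501–1.01, and 0–1 strings were called lower. The nuclear hormone receptors stood at 0.185–0.483 (called on replicate 2 alone and not on replicate 1 alone, so 0–1 lists were called lower) and the cell migration list at 0–1.13.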

Other observations

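All tests in this part were chosen after the main results were seen, except that the forms of 3 of them (forkhead strings on the mitochondrial genome, E2F strings at promoters, and E2F strings at matched CG content) were written down before their own values were known.

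Strings of the E2F type were more frequent at peaks of cell cycle genes than at other promoter peaks. Of the 10 promoter peaks of cell cycle and DNA replication genes 9 carried TTSSCGC in the 200 bp summit window, against 28.0% of other promoter peaks (Fisher's exact adjusted p = 0.0018 over 20 tests of 4 strings in 5 lists). Promoters of cell cycle genes without a peak were not examined. The string may therefore mark promoters of this list whether or not they carry a peak. In the germline list 9 of 14 peaks carried it (64.3% against 28.1%, Fisher's exact adjusted p = 0.058), and in the ribosomal list 3 of 24 (12.5% against 29.4%, Fisher's exact adjusted p = 0.353). Across nuclear peaks the E2F string was more frequent in the 286 peaks of highest signal than in the 287 of lowest signal (31.8% against 19.9%, Fisher's exact adjusted p = 0.0117 over 10 strings). The forkhead consensus stood at 4.90% and 3.14% in those sets and did not pass (Fisher's exact adjusted p = 0.594). The tRNA B box went the other way, at 14.3% in the highest set and 24.0% in the lowest (Fisher's exact adjusted p = 0.0203). The 2 sets were not matched on GC content or annotation class. Among the 584 optimal peaks of highest signal 72.1% were at promoters and 9.42% near tRNA genes, against 66.8% and 13.6% of all. These differences by signal can therefore reflect the mix of classes.

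A scan of all 2080 strings of 6 bases placed alternating CG strings first. GCGCGC occurred in 15.02% of 1145 nuclear summit windows against 3.82% of GC-matched background windows (3.93-fold) and CGCGCG in 13.2% against 3.22% (4.10-fold). The forkhead core TAAACA ranked 536 by p, with 14.9% against 11.9% (1.25-fold, adjusted p = 0.0083 by a normal approximation to permutation within GC classes), and GTAAAC ranked 1330 (1.15-fold). At an adjusted p under 0.05 by that approximation to permutation, 362 strings were higher, TAAACA among them, and 404 lower, and the ranks count both directions. A-rich strings without the AAACA part of TAAACA were raised as well and placed above it, among them AATAAA (1.34-fold) and AAAAAA (1.23-fold). An excess the size of that of the loose forkhead string (1.23-fold) was therefore not limited to forkhead strings. AAAACA (1.37-fold), which shares AAACA with TAAACA, was also placed above it. Peak windows held 10.6 CG dinucleotides on average and background windows 7.53.

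The first pattern weighed is the high signal on the mitochondrial genome. Abundance of mitochondrial DNA in the precipitates relative to the control stays open: optimal entries covered 89.9% of this genome, but that was known before the test was chosen and cannot decide. The signal of its entries was uneven, from 60.04 to 3682, with the same 2 summits highest in both replicates. Whether this unevenness bears on abundance cannot be told, since the lists of both replicates rest on 1 control file that was not analysed. Binding at forkhead strings of this genome stays open, since 26.1% of the mitochondrial summit windows held the loose string against 28.3% of random mitochondrial windows (95% range 13.0–47.8), too few windows to decide. The control reads that bear on both were not analysed here.

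The second pattern is the set of peaks at germline, cell cycle and ribosomal promoters. Forkhead strings as the cause of most peaks were weighed with the loose string alone. It occurred in 27.7% of the 200 bp summit windows, so most peaks lacked it there. Beyond background matches it was present in 6.78% of peaks, below the 50% set for this explanation. Combining opposite ends of the peak interval and the range of draws gave 0.561–12.7%. These values argue against the loose string near the summit as the cause of most peaks. The shares behind them were known before the 50% was set, and other forkhead sites were not counted here. The background is weaker regions of the same experiment, so the excess need not be the share of peaks due to forkhead sites. Signal at accessible or highly transcribed loci whatever the tagged factor stays open: nuclear peaks lay near tRNA genes 7.88 times as often as background regions, but this was known before the test was chosen and cannot decide. No precipitate of an unrelated or untagged protein is among these samples, so binding of UNC-130 through other proteins and a signal common to many precipitates both stay open.

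The third pattern is the frequency of E2F-like strings at summits. Location somewhere in the promoter window is argued against as the whole cause. Among promoter summits the string was 2.42 times as frequent in peaks as in GC-matched background, above the whole 95% range of the draws. Distance to the transcript start was not matched. The promoter fold of peaks rose from 1.88 to 2.23 with windows of 500 bp upstream, so peaks lay closer to starts. Location close to the start therefore stays open. The frequency of CG dinucleotides is argued against as the whole cause, since at matched numbers of CG dinucleotides the string was 1.82 times as frequent in nuclear peaks (23.4% against 12.8%, above all 10000 draws), although the fold was lower than with matching of the same nuclear peaks on GC content alone (2.32). Occupancy of the same promoters by E2F proteins is a candidate explanation that these data did not test.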
